A study of Rattus norvegicus with 6 samples.

How the data were processed

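Skin of a rat model of pressure ulcer was profiled by RNA sequencing in 6 samples, 3 with a pressure injury (PI) and 3 without (non-PI). Per the labels' protocols, RNA with a poly(A) tail was selected, fragmented and copied into cDNA with random primers, and libraries were sequenced on a DNBSEQ instrument. The authors deposited 1 table of RPKM values, with 1 column per sample and a row for each of 23480 rat genes, with Ensembl identifiers, positions and annotation terms. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here, and neither is whether reads or fragments were counted, or whether counting used strand. Groups and replicate numbers come from the sample titles, and columns were matched to samples through the sample descriptions. Symbols were taken from the table, and 156 symbols shared by 408 genes were kept apart by identifier.

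RPKM values are not counts. For short noncoding genes, whose length is their span on the chromosome, low values times the length were whole multiples of 1 number per library, which gives the total the values were divided by. For each other gene the shortest length that gave whole reads in all libraries was taken, within a tolerance of 0.02 reads, and whole reads were recovered in this way for 22887 genes. The other 593 genes were at 0 in all libraries. These totals were 15978866 to 16625783 per library, and the recovered reads made up 99.5% to 99.6% of them. No pair of libraries was a duplicate, with a chi-square per degree of freedom of 72.8 or more between any 2 libraries. Recovered reads served for scaling factors, a filter and voom in alternatives, and a count model was not used.

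The test fixed before the data were examined assumed counts, with a stated form for normalized values, which was used here. Genes with a mean of at least 1 RPKM (14216) were tested on log2(RPKM + 1), with a pseudocount of 1, with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, 2-sided) and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. All 6 samples entered with the group as the only term. The authors' scaling to the assigned total was kept. Fold changes are PI minus non-PI differences on that log2 scale. A test of 3 against 3 by exact permutation cannot go below 0.1, so single list levels were tested that way only for description.

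Gene lists fixed in advance numbered 37, and 33 had at least 3 tested members. They covered immune cells, keratinocytes, hair follicle, glands, fibroblasts, vessels, muscle, fat, nerve and blood, and stress, metabolic and injury responses. The 4 others were the pair in the series title, B and plasma cell markers, melanocyte markers and sex-linked genes. Lists were tested with camera with a preset correlation of 0.01, with camera with an estimated correlation, on ranks and with fry. Fry asks whether the genes of a list shift in a common direction, without other genes for comparison. Terms with 15 to 300 tested genes (1611) were tested with camera. Members of a list were also adjusted over the list alone. At most 3 members of a list occur in another list.

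Genes were named by a rule fixed in advance. It took the pair in the title, the 10 largest increases and 10 largest decreases past an adjusted p of 0.05 with a mean CPM (reads scaled to the library total) of at least 5, groups that do not overlap and a symbol that is not a locus number, and per list the 3 members with the smallest p (4 where 1 was already named). The middle part gave 0 genes, so it was applied again at 0.10 after the data were seen. Other genes were named after the data were seen, where a count of members that passed is spelled out, beside a list as a contrast, as members of lists too small for camera, of terms or of lists used in the closing part, or as called in an alternative.

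The steps were tested on simulated data, with 10 sets of 14216 genes, 3 against 3, and spreads drawn from the prior that limma fitted to these data. Each set held 200 changed genes with a mean of at least 5 RPKM and a list of 20 genes shifted by 2 times. Of genes changed by 2, 4, 8 and 16 times, 20.8%, 79%, 94.6% and 96.8% were recovered at an adjusted p of 0.05, and the shifted list was called in 10 of 10 sets and unshifted lists in 0 of 200 cases. Over the 10 sets, 98 unchanged genes were called. Genes were independent in the simulation, which real genes are not.

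Alternatives planned before the data were examined were a pseudocount of 0.1, no filter beyond 1 read, a mean CPM of at least 1, upper quartile factors, library sizes without the top 1% of genes, voom with sample quality weights, the replicate number as a block, each library left out, and the other set tests. Further ones were chosen after seeing the data, namely other scaling factors, voom without weights or with other filters, log2 CPM, another spread, a higher filter, protein-coding genes alone, and the muscle or hair level as a covariate.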

Results

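RNA was measured by sequencing in skin from a rat model of pressure ulcer, in which tissue is injured by ischaemia followed by reperfusion. The 6 libraries fell into 3 from skin with a pressure injury (PI) and 3 from skin without one (non-PI). The labels do not say whether non-PI skin came from uninjured rats or from another site of injured ones, nor how long after injury skin was taken. Messenger RNA was selected by its poly(A) tail. The values are RPKM, reads or fragments of a gene scaled to its length in kb and to the library's assigned total, for 23480 genes, of which 22887 were above 0 in at least 1 library. Between 15978866 and 16625783 reads stood behind each library, so that 1 read in a gene of 1 kb was worth 0.0602 to 0.0626 RPKM. The labels do not say whether the 3 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be partly technical. Means are given with the SD over n = 3 libraries per group, and fold changes are differences of log2(RPKM + 1) with their SE, which understate the change of genes with low values.

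The comparison asked which genes were expressed at another level in injured skin. Injured skin held more RNA of Serpine1, the inhibitor of plasminogen activators, with 569.6 ± 128 RPKM in PI against 85.3 ± 39.3 in non-PI skin. Ctsl, the lysosomal protease cathepsin L, stood at 1796 ± 579.9 RPKM in PI against 677 ± 126 in non-PI skin. The neutrophil attractant Cxcl6 stood at 61.8 ± 13.5 RPKM against 4.61 ± 3.97, and the glucose transporter gene Slc2a1 at 166 ± 54.2 against 50.98 ± 7.09. Lower in injured skin were the fat cell gene Fabp4, with 163 ± 17.8 RPKM against 462 ± 117, and the collagen gene Col3a1, with 1008 ± 324 against 5016 ± 1475. The 3 libraries of 1 group lay wholly above those of the other for each of these 6 genes. Apart from Serpine1 and Ctsl, which the series title names, they were picked for small p-values in the same data, which favours such separation. It was also seen in 21.7% of all genes tested.

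No single gene passed an adjusted p of 0.05 over the 14216 genes tested with limma. The lowest adjusted p was 0.0578, shared by 44 genes. At an unadjusted p under 0.05 there were 2323 genes, where 711 would be expected by chance, and in 3084 genes (21.7%) the groups did not overlap, where chance gives 10%. Genes vary together, so 711 is only an average. With non-PI 1, non-PI 3 and PI 3 set against the other libraries, 1321 genes had an unadjusted p under 0.05, the most of any mixed split. Voom with sample quality weights called 424 genes at 0.05, 240 higher and 184 lower, and voom without weights called 0. The weights were 1.98, 0.50 and 0.56 for non-PI 1, 2 and 3, and 0.85, 1.97 and 1.09 for PI 1, 2 and 3. The weighted test thus leaned most on non-PI 1 and PI 2. At an adjusted p under 0.10, a level chosen after the data were seen, 252 genes passed, 142 higher and 110 lower in PI skin. That count was 0 without non-PI 1, 886 without non-PI 2, 2 without PI 1, 0 without PI 2 and 0 with the hair follicle level as a covariate. The hair follicle level itself differed between the groups, with means of 7.95 in non-PI and 3.95 in PI libraries. As a covariate it takes up part of the group difference, here and below. Calls lost or directions turned with it therefore do not show that hair accounts for them. The count at 0.05 was 19 without non-PI 3 and 1 (Igsf7, named after its value was seen) without PI 3.

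**Figure D1:**
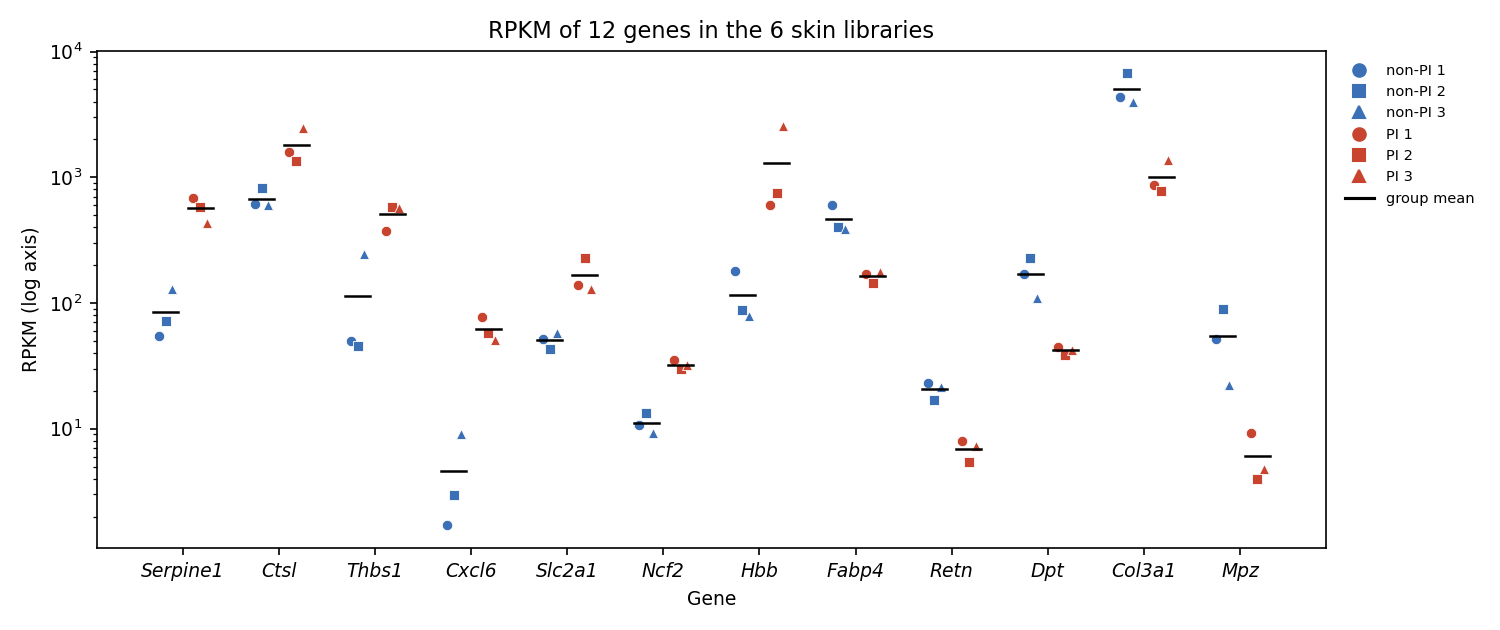
RPKM on a log axis of 12 genes in each of the 6 libraries, with blue points for non-PI and red points for PI skin, a marker shape per replicate number and a black line at each group mean. Serpine1 lay between 54.3 and 129.5 RPKM in non-PI and between 435 and 689.9 in PI skin, while Col3a1 had a mean of 5016 ± 1475 (SD) in non-PI and 1008 ± 324 in PI skin.

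Genes were then grouped into lists fixed before the data were examined, and members were tested both over all genes, where 0 passed, and adjusted over the list alone. Of 465 list members tested, 118 passed adjusted over the list alone. That total was 42, 119, 102, 72, 49 and 97 with 1 library left out and 40 with the hair follicle level as a covariate. Camera, which compares a list with all other genes, called 17 of 33 lists with a preset correlation between genes, 11 higher and 6 lower in PI skin, and 0 with an estimated correlation. Mean levels of some called lists overlapped between the groups. Exact permutation p was 0.5 for heat shock and unfolded protein response and 0.3 for macrophage and monocyte markers. It was also 0.3 for endothelial, pericyte and epidermal differentiation lists, and 0.2 for wound-activated keratinocyte and hair follicle lists. For the other called lists it was 0.1, the lowest possible. Counts with 1 library left out are given here and below in the order non-PI 1, 2 and 3, then PI 1, 2 and 3.

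Serpine1 lies on chromosome 12 from 22641104 to 22651482 (ENSRNOG00000001414) and Ctsl on chromosome 17 from 1872848 to 1879279 (ENSRNOG00000018566), as the deposited table places them, in a genome build not given in the sources used here. Serpine1 read 54.3, 72.04 and 129.5 RPKM in the non-PI libraries and 689.9, 584 and 435 in the PI libraries, a log2 difference of 2.79 ± 0.35 with an adjusted p of 0.0578. Ctsl read 609.7, 823 and 599 RPKM and 1584, 1352 and 2452, a difference of 1.37 ± 0.28 with an adjusted p of 0.1002. Both rose when adjusted over the list alone, with adjusted p = 0.00026 and 0.0022, but the pair is the finding in the study's own title, so its rise here is not independent evidence. Values from whole skin do not show which cells held the RNA. Among coagulation and fibrinolysis genes, 7 of 16 rose adjusted over the list alone (adjusted p = 8.88e-05 by camera, and adjusted p = 0.255 with an estimated correlation). They were Serpine1, Thbs1, Thbd, Plau, Plaur, Anxa2 and Tfpi2. Thbs1, which encodes the platelet and matrix protein thrombospondin, stood at 508 ± 118 RPKM in PI against 113 ± 114 in non-PI skin, Thbd, the thrombin receptor thrombomodulin, at 79.3 ± 32.6 against 32.2 ± 9.83, and the plasminogen activator gene Plau at 80.2 ± 31.7 against 34.3 ± 9.46. With 1 library left out, 1, 1, 6, 6, 1 and 3 members passed. Of 18 cathepsins and their inhibitors, 5 rose (Ctsl, Ctsd, Ctsb, Cstb and Lgmn) and 3 fell (Ctsk, Ctsh and Cst3) adjusted over the list alone. Ctsd stood at 601 ± 171 RPKM in PI against 273 ± 55.4 in non-PI skin and Ctsk, the collagen-degrading cathepsin, at 35.7 ± 3.01 against 124 ± 69.7. Camera did not call that list (adjusted p = 0.476), and 0, 5, 4, 3, 0 and 0 members passed with 1 library left out.

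Cytokine and chemokine genes were higher as a list (27 of 29 had positive differences, adjusted p = 1.52e-08, and adjusted p = 0.405 with an estimated correlation), and 4 of 29 rose adjusted over the list alone. These were Cxcl6, the monocyte attractant Ccl2 with 389 ± 27.5 RPKM in PI against 135 ± 39.7 in non-PI skin, Ccl3 with 32.3 ± 27.5 against 3.40 ± 0.579, and Cxcl3. Leaving out 1 library gave 3, 2, 14, 9, 3 and 3 members. Neutrophil markers were also higher (adjusted p = 2.75e-06, and adjusted p = 0.281 with an estimated correlation). Of 13, 6 rose adjusted over the list alone, among them Ncf2, a subunit of the phagocyte oxidase, with 32.2 ± 2.74 RPKM in PI against 11.1 ± 2.05 in non-PI skin, the myeloid receptor gene Trem1 with 67.7 ± 6.34 against 18.96 ± 5.74 and Csf3r with 65.4 ± 27.4 against 16.9 ± 7.33. That count was 2, 6, 8, 4, 2 and 11 with 1 library left out. Macrophage and monocyte markers gave an adjusted p of 0.00243 (adjusted p = 0.609 with an estimated correlation). Of 16, 3 rose adjusted over the list alone, Cd14, Msr1 and Mrc1, with Cd14 at 177 ± 63.03 RPKM in PI against 50.03 ± 13.4 in non-PI skin. With 1 library left out 0, 7, 7, 4, 0 and 0 passed, and camera's call of the list was lost without non-PI 3 (adjusted p = 0.288). The complement genes C1qa, C1qb and C1qc of the same list had negative differences, C1qc with 61.7 ± 11.3 against 157 ± 103 RPKM. Markers of T and NK cells, mast cells and dendritic cells were not called by camera (adjusted p = 0.361, 0.102 and 0.156). In each, 1 member rose adjusted over the list alone. These were Cd2 with 13.1 ± 5.94 RPKM in PI against 3.73 ± 0.621 in non-PI skin, the histidine decarboxylase gene Hdc with 105 ± 55.9 against 14.4 ± 1.30, while 8 of 9 mast cell markers had negative differences, and Itgax with 22.2 ± 3.07 against 9.18 ± 3.25. Left out in turn, the libraries gave 0, 0, 0, 1, 1 and 1 for T and NK cells and 1, 1, 0, 0, 0 and 1 for dendritic cells. Globin and erythroid genes were likewise higher in each PI library than in any non-PI library, at 5.31, 4.36, 4.52, 5.95, 6.34 and 7.80 on the log2 scale, though within the groups their order was not that of the neutrophil markers. Jchain was the 1 B and plasma cell marker high enough to test, and read 5.56 RPKM in non-PI and 2.93 in PI skin.

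Of 24 hypoxia and glycolysis genes, 17 rose adjusted over the list alone, and all 24 had positive differences (median 0.98, adjusted p = 1.27e-10, and adjusted p = 0.405 with an estimated correlation). Slc2a1 differed by 1.64 ± 0.25, the glycolytic enzyme genes Eno1 and Pgam1 stood at 719.7 ± 202 RPKM in PI against 309 ± 26.6 in non-PI skin and at 423 ± 94.04 against 208 ± 16.05. With 1 library left out, 0, 19, 9, 8, 4 and 17 members passed. Within each group the level of this list was highest in non-PI 2 (6.40) and PI 2 (7.53), which also held the most RNA of skeletal muscle genes (9.73 and 8.37). In the list of oxidative stress defence (adjusted p = 1.49e-04, and adjusted p = 0.281 with an estimated correlation), 5 of 20 rose and 1 fell adjusted over the list alone. The peroxidase gene Prdx1 stood at 456 ± 63.6 RPKM in PI against 235 ± 25.1 in non-PI skin and the superoxide dismutase gene Sod1 at 154 ± 14.1 against 93.2 ± 9.18, whereas Sod3, the extracellular form, stood at 13.2 ± 2.33 against 31.3 ± 8.32. Leaving out libraries gave 2, 7, 4, 0, 0 and 7 members. Cell death genes gave an adjusted p of 6.51e-04 (adjusted p = 0.281 with an estimated correlation), and 6 of 17 rose adjusted over the list alone. Bcl2a1, which restrains apoptosis, stood at 83.8 ± 8.42 RPKM in PI against 32.7 ± 4.67 in non-PI skin, Acsl4, a lipid enzyme needed for ferroptosis, at 44.2 ± 5.13 against 19.2 ± 5.12, and Ripk3, a kinase of necroptosis, at 39.8 ± 6.33 against 20.4 ± 3.99, and 3, 3, 3, 3, 4 and 4 members passed with 1 library left out. Of 17 heat shock and unfolded protein response genes 0 passed adjusted over the list alone, although camera called the list higher (adjusted p = 0.00285, and adjusted p = 0.609 with an estimated correlation). Its members with the smallest p were Sdf2l1, Xbp1 and Ddit3, with Sdf2l1 at 56.2 ± 23.4 against 23.4 ± 0.585 RPKM. Left-out libraries gave 0, 0, 7, 1, 0 and 0 members, and the list's call was lost without non-PI 2 (adjusted p = 0.164).

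All 12 adipocyte markers fell adjusted over the list alone (median -1.46, adjusted p = 8.89e-11, and adjusted p = 0.255 with an estimated correlation). Fabp4 differed by -1.47 ± 0.22, the hormone genes Retn and Lep stood at 6.93 ± 1.32 RPKM in PI against 20.6 ± 3.19 in non-PI skin and at 0.397 ± 0.220 against 3.34 ± 1.27, and 8 to 11 members passed with 1 library left out. Fibroblast and dermal matrix genes were lower as a list (adjusted p = 2.64e-05, and adjusted p = 0.503 with an estimated correlation), and 7 of 13 fell adjusted over the list alone. Dpt, a matrix protein that binds collagen fibres, stood at 41.9 ± 2.91 RPKM in PI against 169 ± 58.8 in non-PI skin, Col3a1 differed by -2.32 ± 0.32 and Col1a1 stood at 1576 ± 636 against 5641 ± 641, whereas Dcn stood at 2047 ± 1093 against 1446 ± 240.0 and Pdgfra at 53.5 ± 25.6 against 48.97 ± 29.1. With PI 2 or PI 3 left out the count was 4. Matrix remodelling and myofibroblast genes moved both ways, and camera did not call them (adjusted p = 0.394). Adjusted over the list alone, Timp1, Tnc, Thbs1 and Mmp3 rose and Sparc, Postn and Tagln fell, with Timp1, an inhibitor of metalloproteases, at 1058 ± 269 RPKM in PI against 252 ± 77.9 in non-PI skin, Tnc at 185 ± 91.8 against 41.7 ± 15.5 and Sparc at 1286 ± 157 against 4002 ± 438. That count of 7 was 3, 10, 7, 4, 7 and 4 with 1 library left out. Schwann cell markers were lower (adjusted p = 0.00114, and adjusted p = 0.405 with an estimated correlation), and 3 of 6 fell adjusted over the list alone. These were S100b with 4.96 ± 1.93 RPKM in PI against 18.2 ± 2.97 in non-PI skin and the myelin genes Mpz with 6.03 ± 2.87 against 54.4 ± 33.4 and Mbp with 6.01 ± 1.54 against 11.2 ± 3.35. Leaving out non-PI 2, PI 2 or PI 3 left it at 2. Endothelial markers were called higher (adjusted p = 0.00440, and adjusted p = 0.609 with an estimated correlation), and Emcn, Eng and Flt1 rose adjusted over the list alone. Eng stood at 120.1 ± 17.7 RPKM in PI against 66.8 ± 10.3 in non-PI skin and Flt1, a receptor for vascular growth factors, at 28.97 ± 9.91 against 12.2 ± 3.37. The direction of that list turned with the hair follicle level as a covariate, to a median of -0.20, its call was lost without non-PI 3 or PI 1, and its members passing numbered 0, 3, 0, 0, 0 and 3 with 1 library left out. Pericyte and smooth muscle markers had an adjusted p of 0.0465 (adjusted p = 0.609 with an estimated correlation) and a median of -0.42, and that call was lost without non-PI 2, PI 1 or PI 3 and with upper quartile factors, among other settings. Of these 8 members 0 passed adjusted over the list alone (3 without PI 2), and Cnn1 stood at 5.82 ± 2.64 against 13.2 ± 3.33.

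Hair follicle genes and hair keratins had the most negative median of the 33 lists, -4.05 (adjusted p = 1.27e-10, and adjusted p = 0.503 with an estimated correlation). All 19 fell adjusted over the list alone, but 0 did without non-PI 1, non-PI 3, PI 1 or PI 2. The mean log2(RPKM + 1) of the list was 8.78, 6.60, 8.46, 1.52, 3.40 and 6.94 in the 6 libraries in the same order, so that PI 3 lay above non-PI 2, with an exact permutation p of 0.2 (2-sided, where 0.1 is the lowest that 3 against 3 allows). Lef1, a transcription factor of the hair matrix, stood at 4.48 ± 4.23 RPKM in PI against 29.2 ± 12.9 in non-PI skin and Hoxc13, which controls hair keratins, at 6.93 ± 9.00 against 47.8 ± 23.6. Some hair keratin genes may be alike in sequence, so reads may be split between them, which was not examined. Epidermal differentiation genes were called lower (adjusted p = 0.00367, and adjusted p = 0.609 with an estimated correlation), a call lost without non-PI 3 and with the hair follicle level as a covariate. Of 13, 0 passed adjusted over the list alone (0, 6, 0, 0, 0 and 2 with 1 library left out), with Krt2 at 0.567 ± 0.366 RPKM in PI against 2.81 ± 1.08 in non-PI skin and the desmosome gene Dsc1 at 8.40 ± 3.73 against 26.5 ± 14.6. Wound-activated keratinocyte genes were called higher (adjusted p = 2.07e-04, and adjusted p = 0.503 with an estimated correlation). The integrin gene Itga5 with 65.7 ± 7.80 RPKM in PI against 29.6 ± 3.15 in non-PI skin and the protease gene Mmp10 with 9.02 ± 2.23 against 0.911 ± 1.03 rose adjusted over the list alone. S100a8, which neutrophils also express, read 118, 72.6, 245, 645, 566 and 233 RPKM in the 6 libraries, and the neutrophil markers had mean levels of 3.50, 3.22, 4.05, 4.82, 4.83 and 4.41 on the log2 scale. The count of members that passed, 2, was 2, 3, 7, 2, 2 and 3 with libraries left out. Basal keratinocyte markers were not called (median 0.38, adjusted p = 0.274), and Krt14 stood at 539 ± 261 RPKM in PI against 297 ± 188 in non-PI skin. Sebaceous gland markers were not called either (adjusted p = 0.839), and adjusted over the list alone the desaturase gene Scd fell, with 45.9 ± 19.8 against 179 ± 65.1 RPKM, and Soat1 rose, with 78.6 ± 13.5 against 44.1 ± 7.08. With libraries left out, 0, 3, 1, 2, 0 and 0 of its members passed.

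**Figure D2:**
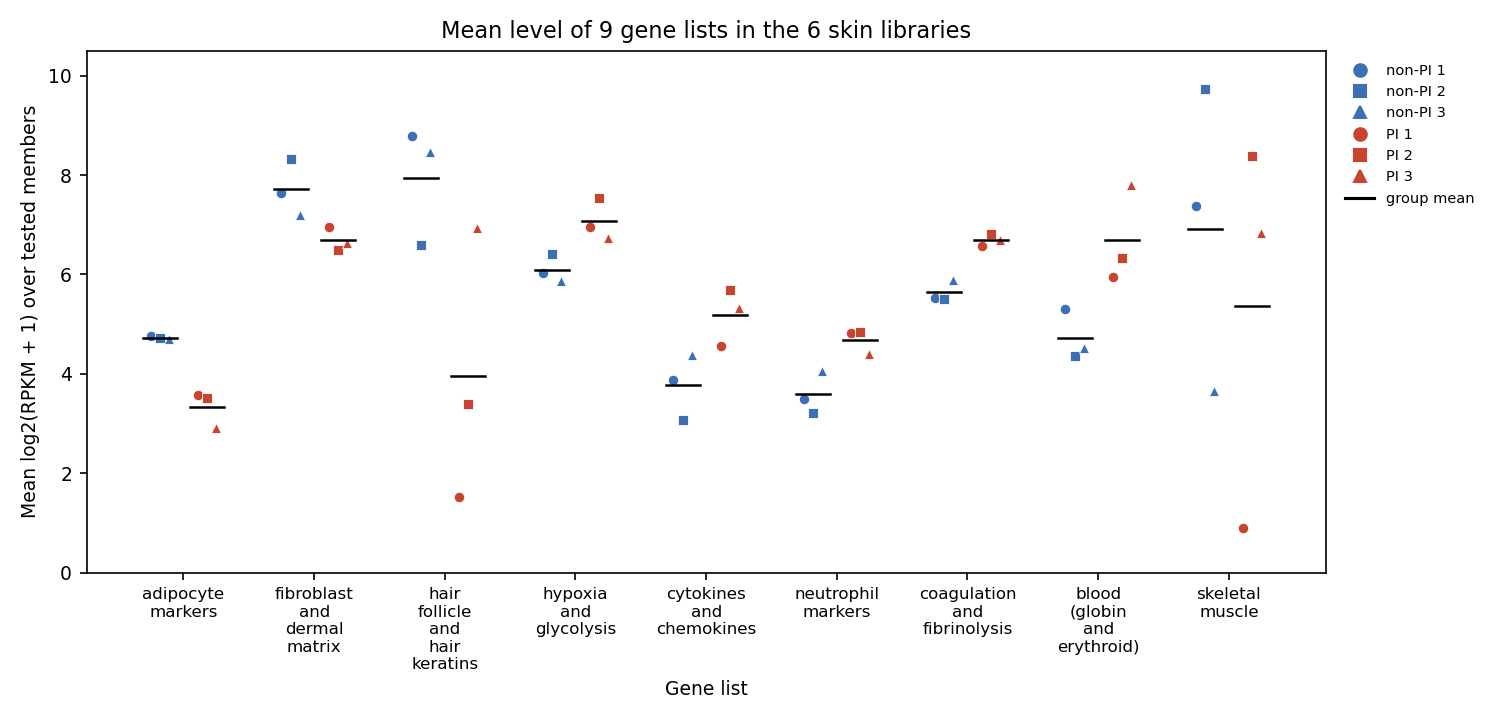
Mean log2(RPKM + 1) over the tested members of 9 gene lists in each of the 6 libraries, with blue points for non-PI and red points for PI skin, a marker shape per replicate number and a black line at each group mean. Skeletal muscle genes ran from 0.90 in PI 1 to 9.73 in non-PI 2, and adipocyte markers from 2.90 to 3.58 in PI and from 4.69 to 4.77 in non-PI skin.

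Levels of skeletal muscle genes differed widely within both groups, with means of 7.37, 9.73, 3.65, 0.90, 8.37 and 6.83 on the log2 scale, and the list was not called (median -1.72, adjusted p = 0.102, exact permutation p = 0.6). Camera called that list lower without non-PI 3, PI 2 or PI 3. Casq1, which binds calcium in skeletal muscle, read 83.4, 591, 5.29, 0.732, 126 and 24.8 RPKM. The blood list was higher in PI skin (median 2.55, adjusted p = 0.00243, and adjusted p = 0.503 with an estimated correlation), and 4 of 5 rose adjusted over the list alone. Hbb, a globin gene, stood at 1296 ± 1075 RPKM in PI against 116 ± 55.00 in non-PI skin, Hba-a1 and Hba-a2 are near-identical copies whose reads cannot be told apart with certainty, Alas2 was the other that passed, and Slc4a1 stood at 0.999 ± 0.840 against 1.43 ± 0.890. Immediate early genes (adjusted p = 0.102), interferon response (0.213), oxidative phosphorylation (0.107), mitochondrially encoded genes (0.169), cholesterol synthesis (0.789), barrier lipid synthesis (0.212), circadian clock (0.839) and proliferation (0.962) were not called, and 0 of their members passed adjusted over the list alone. Interferon response genes stood apart in non-PI 1, with list means of 5.70, 3.00, 3.21, 3.45, 3.43 and 3.80, and its Cxcl9 read 41.04, 12.97, 5.34, 3.48, 3.65 and 4.65 RPKM. That list was called higher without non-PI 1 (adjusted p = 0.0493) and lower without non-PI 2 or non-PI 3. Proliferation was called higher without PI 1 (adjusted p = 0.0311) and lower without PI 2. Ier3 stood at 134 ± 64.9 RPKM in PI against 43.5 ± 21.02 in non-PI skin, Mcm5 at 13.3 ± 4.41 against 8.94 ± 1.47, Idh3a at 41.9 ± 6.84 against 58.5 ± 10.7, Ldlr at 67.00 ± 9.13 against 43.04 ± 9.60, Fasn at 23.8 ± 1.86 against 45.02 ± 13.2 and Dbp at 22.6 ± 2.27 against 16.2 ± 5.74. Median, mean and camera direction differed in sign for sebaceous gland, proliferation and cholesterol synthesis genes. Of the melanocyte markers 2 were tested, too few for camera, and they lay in opposite directions. Dct read 2.13 RPKM in non-PI and 0.662 in PI skin, and Pmel 1.15 in non-PI and 2.78 in PI skin. The Y-linked genes Kdm5d and Eif2s3y were read in all 6 libraries, Eif2s3y with 49.1, 43.6, 49.7, 72.04, 51.4 and 53.6 RPKM. The Y-linked gene Ddx3y lay below the filter, with means of 0.064 RPKM in non-PI and 0.0575 in PI skin.

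Gene annotation terms carried by the deposited table were tested in the same way. Camera called 124 of 1611 terms, 86 higher and 38 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.736. Without non-PI 3 the count was 70. Among the terms called higher, neutrophil chemotaxis held 43 tested genes, 22 of them higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 1.33e-06, and adjusted p = 0.736 with an estimated correlation), and glycolytic process held 34, 13 of them higher and 0 lower (adjusted p = 6.76e-04, and adjusted p = 0.837 with an estimated correlation). Among those called lower, keratin filament held 63 genes, 41 of them lower and 2 higher (adjusted p = 9.83e-13, and adjusted p = 0.832 with an estimated correlation), and collagen trimer held 45, 18 of them lower and 5 higher (adjusted p = 8.33e-04, and adjusted p = 0.829 with an estimated correlation).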

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

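All 252 genes past 0.10 kept their direction in each setting in which they were tested. They were selected for separation in these same data, which makes that likely. The median difference of all genes stayed within 0.1 of 0. Serpine1 kept log2 differences of 2.40 to 3.14 over 30 alternatives (adjusted p = 0.0274 to 0.494, past 0.05 in 5) and Ctsl 1.13 to 1.69 (adjusted p = 0.0468 to 0.504, past in 4). All 4 passes of Ctsl, and 4 of the 5 of Serpine1, came from forms of voom with sample quality weights. The remaining pass of Serpine1 was without non-PI 3. The 2 count tools chosen before the data were examined were not run because the values are not counts, and the total count, also chosen then, is the scaling of the test itself. Settings described as added were chosen after seeing the data. A gene of 1 kb at 1 RPKM rests on 16 or 17 reads, so depth limits what can be said of genes near the filter. Why results moved was not examined further, and the cause was not tested.

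At 0.05, where the test named 0 genes, voom with sample quality weights named 424. Added forms named 427 with column sums, 476 with a mean CPM of at least 1, 476 with a mean over 16 reads, and 3 (Sprr1b, Slc6a14 and LOC102550416, all higher) with the muscle and hair levels as covariates. Leaving out a library gave 0 to 19. At 0.10, against 252, the count was 32 without a filter, 1430 with quality weights, and among added settings 1432 with column sums, 1573 and 1574 with the other 2 filters, 165 by voom without weights with a mean CPM of at least 1, 99 with the muscle level, 0 with the hair level and 3 with both as covariates. Left-out libraries gave 0 to 886. Of the 114 named genes, 48 passed with quality weights, 48 with column sums and 50 with each of the other filters, and 0 to 10 with a library left out. Lists called fell from 17 to 0 with an estimated correlation and to 2 (adipocyte markers and coagulation, adjusted p = 0.0283 each) by fry, and numbered 20 on ranks. That fry count is for a shift in a common direction. Without regard to direction, fry gave low values for further lists, such as adjusted p = 0.00125 for matrix remodelling genes and 0.00256 for cathepsins. Terms called fell from 124 to 0 with an estimated correlation, and lay between 70 and 142 with a library left out.

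The replicate number as a block, with 3 pairs, gave 0 genes at 0.05 and 0 at 0.10, with a lowest adjusted p of 0.131 and 20 lists called. Deviations of samples with the same number correlated at -0.18, 0.50 and -0.06. Of the non-PI samples, non-PI 1 and non-PI 3 correlated best with another number than their own. With 3 samples per group, such values do not show whether samples with the same number came from the same animal.

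A gene's direction is counted as turned where its difference changed sign, and a list's where camera's direction did, which need not change the sign of the median printed. With the hair level alone, and with the muscle and hair levels, as covariates, differences became -0.0169 and -0.0277 for Batf3, 0.0145 and 0.0546 for Pnpla1, -0.16 and -0.16 for Clock, and -0.11 and -0.11 for Mt-nd4. List medians became -0.20 and -0.22 for endothelial markers, 0.34 and 0.40 for interferon response, 0.0449 and 0.0153 for oxidative phosphorylation, 0.13 and 0.15 for cholesterol synthesis, 0.13 and 0.19 for barrier lipid synthesis, 0.24 and 0.23 for proliferation, and 0.0749 and 0.11 for sebaceous gland markers. Skeletal muscle became 0.53 with the hair level, and matrix remodelling genes 0.10 with both. Sebaceous gland markers became 0.0913 with the muscle level and -0.42 with a mean of at least 5 RPKM. For proliferation the median was 0.0755 in the test itself and, with camera's direction turned, 0.0755 without a filter, with a mean CPM of at least 1, with the block and by fry, 0.0911 with the muscle level, and 0.12 to 0.13 with quality weights. The circadian clock median became 0.0553 with quality weights, 0.0545 with column sums, and 0.0581 and 0.058 with the other 2 filters.

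With a library left out, the ranges of differences or medians, for genes and lists whose direction turned in this sense, were -4.07 to 0.20 for Atp2a1, -0.14 to 0.23 for T and NK cell markers, 0.0229 to 0.66 for basal keratinocyte markers, 0.0046 to 0.55 for sebaceous gland markers, -3.42 to 0.77 for skeletal muscle, 0.11 to 0.43 for cathepsins, -0.19 to 0.24 for proliferation, -1.24 to 0.30 for interferon response, -0.23 to 0.14 for cholesterol synthesis and -0.12 to 0.0452 for circadian clock genes. Medians also crossed 0 while camera's direction held, to -0.0277 for dendritic and Langerhans cell markers and 0.0788 for hair follicle genes with the muscle and hair levels as covariates. The median of skeletal muscle crossed 0 in that setting too. Others went to -0.0116 for immediate early genes without PI 3, and to 0.0062 for oxidative phosphorylation and 0.20 for barrier lipid synthesis with a library left out.

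Lists the test did not call were called in some settings. With a library left out, camera called skeletal muscle lower (without non-PI 3, PI 2 or PI 3), mast cell markers lower (non-PI 3 or PI 2), oxidative phosphorylation lower (non-PI 3 or PI 3), barrier lipid synthesis lower (non-PI 2), basal keratinocyte markers higher (non-PI 3), matrix remodelling genes higher (non-PI 2), immediate early genes higher (non-PI 3 or PI 1), and interferon response and proliferation either way. With the hair level as a covariate it called mast cell markers lower and immediate early genes, cathepsins and proliferation higher. Quality weights gave a call of interferon response as lower, and a mean of at least 5 RPKM of T and NK cell markers as higher. The block and the ranks each called mast cell markers and skeletal muscle lower and immediate early genes higher.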

Other observations

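Read as biology, the genes and terms below were picked after the results were seen, and none passed 0.05 over all genes. Keratin-associated proteins, which crosslink keratin in the hair shaft, followed the hair keratins. All 30 with a symbol starting Krtap had negative differences (median -4.86), 28 at an unadjusted p under 0.05, but the groups did not overlap in only 10, and their mean level of 5.20 in PI 3 lay above the 4.88 of non-PI 2. Some of these genes may be alike in sequence, so single values may mix them, which was not examined. The term for smoothened signalling, the hedgehog pathway that drives follicle growth, was called lower (50 genes, median -0.27, adjusted p = 8.41e-05, and adjusted p = 0.736 with an estimated correlation). Its Gli1 stood at 1.96 ± 1.22 RPKM in PI against 9.42 ± 1.16 in non-PI skin, Ptch1 at 3.42 ± 0.841 against 12.96 ± 3.20, Shh at 1.28 ± 1.08 against 8.27 ± 2.38 and Smo at 7.75 ± 1.38 against 13.9 ± 1.67. Wnt-protein binding was called lower too (22 genes, median -0.67, adjusted p = 8.33e-04, and adjusted p = 0.736 with an estimated correlation), with Ror2 at 2.61 ± 0.518 RPKM in PI against 6.98 ± 1.33 in non-PI skin and Fzd1 at 12.9 ± 4.64 against 26.3 ± 1.49. Of its members at an unadjusted p under 0.05, 9 were lower and 1 was higher, Ptpro, with 17.96 ± 3.77 against 7.17 ± 3.01 RPKM.

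Ferric iron binding was called higher (16 genes, median 1.22, adjusted p = 4.97e-07, and adjusted p = 0.778 with an estimated correlation), mostly through ferritin-like copies that cannot be told apart with certainty. LOC100360087 stood at 1697 ± 268 RPKM in PI against 605 ± 166 in non-PI skin and Ftl1 at 19.6 ± 1.64 against 7.80 ± 0.605. The genes that follow were named by the rule at 0.10, which ranks by size of difference. Arg1, an arginase, stood at 192 ± 86.02 RPKM in PI against 24.3 ± 3.83 in non-PI skin (adjusted p = 0.0625), the platelet factor gene Pf4 at 605 ± 126 against 99.7 ± 30.01, the protease gene Adam8 at 163 ± 19.4 against 29.8 ± 14.6, the activin gene Inhba at 20.6 ± 2.58 against 3.96 ± 3.22 and the receptor gene Havcr2 at 20.1 ± 5.73 against 3.59 ± 1.99. On the lower side the rule named Krtap12-2 and Gm4553 first (log2 differences of -5.11 each, adjusted p = 0.0901 and 0.0672). Krtap12-2 is a shared symbol, and the value is that of ENSRNOG00000057487. It also named the microfibril gene Mfap2 with 3.10 ± 1.52 against 68.00 ± 20.9 RPKM (adjusted p = 0.0578), the lipogenic gene Thrsp with 7.86 ± 4.23 against 74.5 ± 22.05, Rbp4 with 9.32 ± 1.25 against 53.6 ± 12.5, Fndc1 with 2.16 ± 0.809 against 30.7 ± 19.1, Itm2a with 22.3 ± 6.16 against 132 ± 65.8 and Clec11a with 2.58 ± 1.64 against 16.2 ± 4.91.

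Hair follicle genes were lower in PI skin, and of the 2 tests of causes, the follicle stem cell list was fixed before its result was seen and the basal keratinocyte comparison was chosen after. A fall of all keratinocytes as large as that of hair genes is argued against by the basal keratinocyte median of 0.38 beside -4.05. The basal quartiles of 0.17 and 0.57 are over genes, and basal levels overlapped between the groups (exact permutation p = 0.7). Epidermal differentiation genes were lower, with a median of -0.74 (quartiles -0.98 and -0.11), so a smaller loss of keratinocytes is not excluded. Whether there were fewer follicles of every stage stays open. The stem cell list had a median of -0.70 (quartiles -1.02 and 0.38), with Lgr5, Lhx2, Tcf7l1 and Cd34 lower and Nfatc1 higher at an unadjusted p under 0.05. These values met the limits fixed beforehand for arguing against fewer follicles. On this scale a complete loss would bring the median to -3.09 (quartiles -4.97 and -2.83), so a complete loss of the RNA of this list is argued against. Fewer follicles are not excluded, since Lgr5, Lhx2, Tcf7l1 and Cd34 were lower. Krt15 is also a basal keratinocyte marker whose level outside the follicle would hide a loss. Whether RNA of the other members came from cells outside the follicle was not examined. The list therefore cannot decide how many follicles there were. Follicles in another phase of the hair cycle, or hair shafts lost from injured skin, might give the same picture, and neither was tested.

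Skeletal muscle genes varied within both groups, and the test with further muscle genes was fixed before its result was seen, the permutation test after. Muscle genes outside the list were higher in non-PI 2 than in non-PI 3 by a median of 4.24 (quartiles 3.56 and 6.26), as muscle in some tissue pieces would give. Those 2 libraries held the highest and lowest levels of the list in the non-PI group (9.73 and 3.65). Muscle genes tend to vary together, so that outcome was likely in advance and adds little weight. A difference between the groups could not by itself give a spread within them. The difference was -1.55 beside an SD of 3.53 within groups (exact permutation p = 0.6). That test was chosen after the overlapping levels were seen, so it adds no weight. A difference between the groups is not excluded.

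Adipocyte genes were lower in PI skin, and the test with the muscle covariate was fixed before its result was seen, the keratinocyte comparison after. Basal keratinocyte genes lay 1.84 above adipocyte genes in median difference. That argues against an equal fall of all resident skin cells, basal keratinocytes included. Fibroblast and dermal matrix genes were lower too, with a median of -1.13 (quartiles -1.82 and -0.39). A lower share of fat and dermal cells together is therefore not argued against. With the muscle level as a covariate the adipocyte median was -1.50 (quartiles -1.76 and -1.05). Within groups the muscle level did not track the adipocyte level. Adipocyte levels in non-PI 1, 2 and 3 were 4.77, 4.72 and 4.695, beside muscle levels of 7.37, 9.73 and 3.65. That covariate therefore cannot decide whether PI pieces held less of the layer of fat and muscle, which stays open. Fat cells that were lost and fat cells that turned their genes down cannot be told apart here (basal minus adipocyte 1.84 in either case).

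The 6 samples can be divided into 3 and 3 in only 10 ways, too few for a share under 0.05. The splits for terms and for list members were fixed before they were run, and the others were added after. Genes past 0.05 numbered 0 in the real grouping and at most 0 in the others, so all 10 splits reached it. At 0.10 there were 252 genes in the real grouping and at most 1 in another, so 1 split reached it, that of the labels. Terms called were 124 against at most 97 (1 split), and list members that passed adjusted over the list alone were 118 against at most 35 (1 split). Lists called by camera were 17 against at most 17 (3 splits), so the count of lists called with the preset correlation does not separate the real grouping from mixed ones.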
